A study of Mus musculus with 6 samples.

How the data were processed

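The libraries were made from Kupffer cells, the resident macrophages of the liver, sorted by flow cytometry from C57BL/6 mice that carried Hepa1-6 tumours, a mouse hepatoma line. The tumour cells held an empty vector in the KC_EV group or overexpressed erythropoietin in the KC_Epo group, and livers were taken on day 18. Each group had 3 libraries. The labels number the mice within a group; as nothing else in them says that each library came from a separate animal, the p-values measure the spread between these libraries.

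Per the labels' protocols, polyA RNA was made into stranded libraries with the Illumina TruSeq stranded mRNA kit. The submitters' processing notes name FastQC 0.11.8, Bowtie2 2.5.1, STAR 2.7.3a, HTSeq 0.11.2 and the mouse build GRCm39, with no role or order, and the counting options are not given in the sources used here. The deposited table holds whole-number read counts per gene symbol that were not normalized, for 15458 rows. The row totals start at 5 counts and 489 rows held fewer than 10 counts. 12 symbols stood on 2 rows; the row with more counts kept the symbol and the other was tested under a separate name. Genes with near-identical copies, among them the globin, Hspa1, Cyp2c, Cyp4a, Orm, Saa, Tgtp and H2-Q genes, can share reads, and their single values are uncertain for that reason. The reference annotation at hand was for another build than the authors', so no coordinates are given.

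Total counts per library were 30229989, 29327625 and 32199405 in KC_EV 1 to 3 and 32445139, 33280754 and 23201076 in KC_Epo 1 to 3. Counts were analysed in R 4.3.3 with edgeR 4.0.16: TMM factors, filterByExpr with default settings, a robust quasi-likelihood fit and a two-sided F test, with Benjamini-Hochberg adjustment over the 13120 genes tested and a threshold of 0.05. No block was used. Standard errors of log2 fold changes were taken from the F statistic. Levels are TMM-scaled CPM, given as mean ± SD over 3 libraries. Within a group, library pairs differed by far more than sampling noise (chi-square per gene of 6.14 or more), so none was a copy of another, which does not show that they came from separate animals. Intervals and floors from counts cover counting error only; the floor was 3 counts over the group, and intervals were exact at 95%.

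Gene lists for pathways and for cell types were fixed before the data were examined, as were the tests and the alternatives unless stated otherwise. 33 lists with at least 4 tested members were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 33 lists, and again with the correlation estimated per list; fry was run beside it. The named genes were the 12 largest rises and the 12 largest falls among genes past the threshold with at least 5 CPM in the higher group and no overlap between groups, leaving out predicted genes, pseudogenes and receptor or antibody segments. To these came up to 3 members of each list with the smallest adjusted p, and Epor, Epo, Nfe2l2, Hmox1, Slc40a1, Spic, Clec4f, Timd4, Cd163, Mrc1, H2-Ab1 and Cxcl9 in every case. Genes outside this rule are marked where they appear, and some genes that the rule names are not reported here.

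The procedure was tested on simulated counts with known changes for this comparison, over 13169 genes. It recovered 58% of genes raised 1.5-fold, 75.5% of those raised 2-fold, 98% of those raised 4-fold and 77.6% of those lowered to 0.5, and called 0.0386% of unchanged genes. Only 49 or 50 tested genes were changed per fold, from a single mean profile with no shift of library composition. In the real data 32.3% of genes were called and composition split by group, so these rates need not hold there. Alternatives were other size factors (RLE, upper quartile, library sizes only, and library sizes without hepatocyte, erythroid and immunoglobulin genes), no filter or a filter of 1 CPM in 3 libraries, a non-robust fit, a replicate block, a test against a 1.2-fold change, a prior count of 0.5, DESeq2 1.42.0, limma-voom and each library left out in turn. Leaving out KC_EV 1 and KC_Epo 1 together was added after seeing the data.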

Results

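Messenger RNA was measured in 6 libraries of sorted Kupffer cells, 3 from mice with control Hepa1-6 tumours (KC_EV) and 3 from mice whose tumour cells overexpressed erythropoietin (KC_Epo), the hormone that drives red cell formation. Depth ran from 23201076 to 33280754 counts per library. The first principal component held 63.6% of the variance and separated the groups, and the second held 15.0%. The comparison asks how Kupffer cell expression differed when the tumour produced erythropoietin.

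In KC_Epo, genes of heme and iron handling, lysosomes and Kupffer cell identity were higher, and MHC class II, inflammatory and cell cycle genes were lower. With an estimated correlation 0 of these lists passed, the lowest adjusted p being 0.329. Hmox1, the enzyme that breaks down heme, rose from 1296 ± 47.4 CPM to 4830 ± 245 CPM (SD, n = 3 each). H2-Eb1, an MHC class II chain that presents peptides to T cells, fell from 1954 ± 59.5 CPM to 382 ± 38.9 CPM. Transcripts of red cells and hepatocytes were higher in the same libraries, and those of sinusoidal endothelial cells were lower. By the edgeR quasi-likelihood test, 4234 of 13120 genes passed an adjusted p of 0.05, of which 2219 were higher and 2015 lower. Of these, 357 rose and 877 fell more than 2-fold. The groups did not overlap for 6338 genes, 48.3% of those tested, where chance gives 10%. Without KC_Epo 3 the count was 2728, with 1477 higher and 1251 lower. The share of calls that were higher was 52.4%, against 40.6% with upper-quartile factors and 24.9% with library sizes only, where the median of all genes shifted from -0.0045 to -0.16 on the log2 scale. Library composition split by group: TMM factors were 1.05 to 1.067 in KC_EV and 0.934 to 0.959 in KC_Epo. The 20 highest genes held 10.65 to 11.18% and 13.33 to 13.46% of counts, and ribosomal protein genes 3.31 to 3.38% and 2.61 to 2.93%.

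Erythropoietin and its receptor were read first as a check of the groups. Epo had 0 counts in each KC_EV library and 29, 44 and 21 counts in KC_Epo 1 to 3, at least 36.1-fold higher against a floor of 3 counts over the KC_EV group. Epor, the erythropoietin receptor, rose by a log2 fold change of 1.18 ± 0.14 (SE, edgeR adjusted p = 7.52e-05), from 12.9 ± 2.65 to 29.4 ± 1.62 CPM (SD, n = 3). In the list of receptor and STAT5 signalling genes, 5 of 14 tested members rose and 4 fell, the same counts adjusted over the list alone, and the list as a whole did not pass (camera adjusted p = 0.21; adjusted p = 0.385 with an estimated correlation). Among its members Socs2, a feedback inhibitor induced by STAT5, rose by 1.77 ± 0.09 and Csf2rb, a shared cytokine receptor chain, by 1.00 ± 0.07. Pim1, a kinase, rose by 0.83 ± 0.08. Epo counted among the members that rose. The 4 that fell, outside the naming rule, were Socs1 at -1.39 ± 0.19, Jak2 at -0.51 ± 0.08, Pim2 at -0.48 ± 0.17 and Cish at -0.39 ± 0.12.

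Heme and iron genes rose as a group, with 12 of 22 members higher and 1 lower, or 14 and 1 adjusted over the list alone (camera adjusted p = 0.00051; adjusted p = 0.329 with an estimated correlation). Hmox1 had a log2 fold change of 1.90 ± 0.08 (SE, edgeR adjusted p = 3.69e-08). Slc48a1, which moves heme out of the lysosome, rose by 1.57 ± 0.09, Tfrc, the transferrin receptor, by 1.02 ± 0.09 and Slc40a1, the iron exporter ferroportin, by 0.87 ± 0.09. Spic, a transcription factor of iron-recycling macrophages, did not pass the test at 0.13 ± 0.08 (adjusted p = 0.243). The member that fell, outside the naming rule, was Hamp, hepcidin, with 242 counts in KC_EV and 1 in KC_Epo. In the heme biosynthesis list 2 of 11 members rose and 0 fell, 0 in either direction adjusted over the list alone, and the list did not pass (camera adjusted p = 0.735; adjusted p = 0.863 with an estimated correlation). Of the NRF2 pathway, which answers oxidative stress, 18 of 25 members rose and 4 fell, the same adjusted over the list alone (camera adjusted p = 5.95e-05; adjusted p = 0.329 with an estimated correlation). Txnrd1, a thioredoxin reductase, rose by 0.81 ± 0.07 and Gclm, of glutathione synthesis, by 1.03 ± 0.09. Nfe2l2, which encodes NRF2 itself, fell by 0.22 on the log2 scale (adjusted p = 0.0428), a call that was lost without KC_EV 1, KC_EV 2, KC_EV 3, KC_Epo 2 or KC_Epo 3, where the adjusted p reached 0.16.

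**Figure D1:**
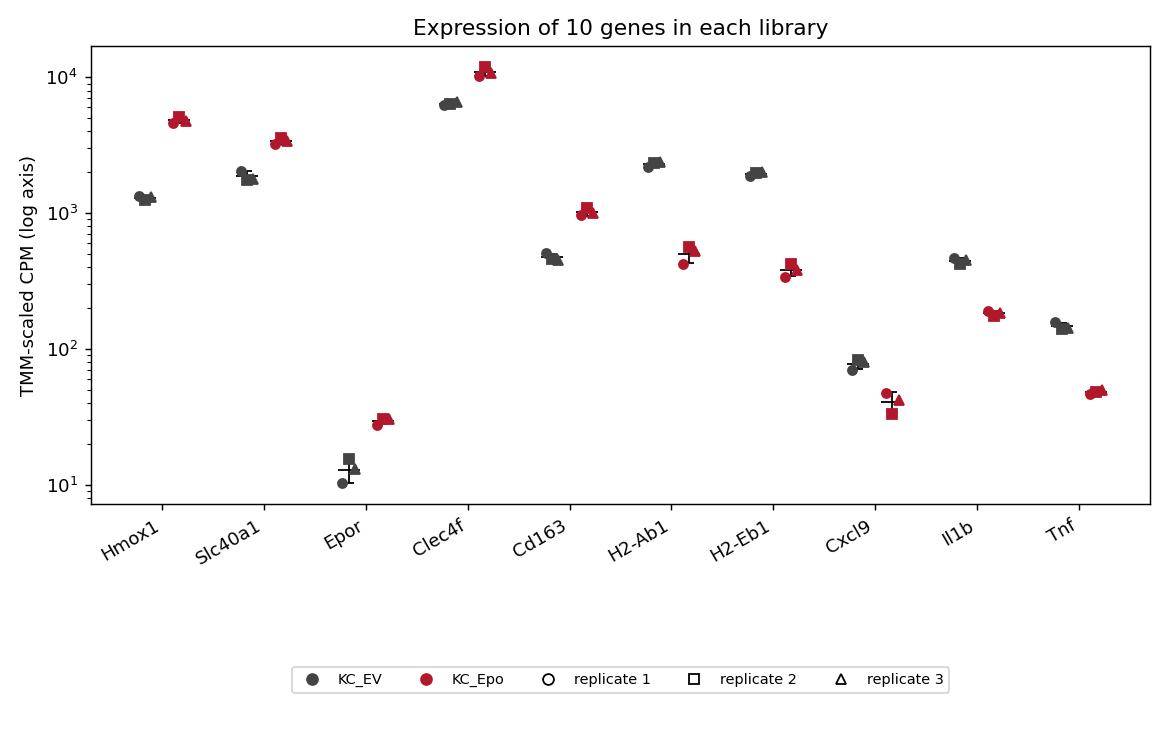
TMM-scaled CPM of 10 genes in each library, on a log axis, with KC_EV in grey and KC_Epo in red; marker shape gives the replicate number and black bars the mean ± SD of 3 libraries. Hmox1 lies at 1296 CPM on average in KC_EV and 4830 CPM in KC_Epo, and H2-Ab1 at 2301 and 503 CPM.

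Of 21 Kupffer cell identity genes, 17 rose and 0 fell, the same adjusted over the list alone (camera adjusted p = 1.72e-07; adjusted p = 0.329 with an estimated correlation). Cd163, the haptoglobin-hemoglobin receptor, rose by 1.11 ± 0.08, Fcna, a ficolin, by 1.11 ± 0.11 and Clec4f, a lectin of Kupffer cells, by 0.79 ± 0.09. Il18bp, which neutralises interleukin 18, rose by 0.90 ± 0.09. A larger share of Kupffer cells in the KC_Epo sorts was not separated from higher expression per cell. Timd4, a receptor for phosphatidylserine, did not pass at 0.16 ± 0.08 (edgeR adjusted p = 0.152) but passed without KC_EV 1 (0.24, adjusted p = 0.0349). Mrc1, the mannose receptor, rose by 0.30 ± 0.08, and lost its call without KC_EV 3 (0.26, adjusted p = 0.0687). Lysosome genes rose in 20 of 26 cases and fell in 1, the same adjusted over the list alone (camera adjusted p = 1.72e-07; adjusted p = 0.329 with an estimated correlation), with Ctsd at 1.34 ± 0.10 and Ctsb at 1.02 ± 0.10, both cathepsins, and the lipase Lipa at 1.01 ± 0.09. Of 22 phagocytosis and efferocytosis receptors 14 rose and 3 fell, or 14 and 4 adjusted over the list alone (camera adjusted p = 0.000379; adjusted p = 0.329 with an estimated correlation). Cd300lf rose by 1.16 ± 0.07, Msr1, a scavenger receptor, by 0.66 ± 0.07 and Mertk, which binds dying cells through bridging proteins, by 0.64 ± 0.07. LXR targets and lipid export genes rose in 10 of 13 cases and fell in 1, or 11 and 1 adjusted over the list alone (camera adjusted p = 0.000114; adjusted p = 0.329 with an estimated correlation), with Apoe at 0.81 ± 0.08 and Apoc1 at 0.78 ± 0.07. Lpcat3, a phospholipid-remodelling enzyme, rose by 0.71 ± 0.07.

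MHC class II presentation fell in 11 of 14 genes and rose in 1, or 11 and 2 adjusted over the list alone (camera adjusted p = 0.000333; adjusted p = 0.385 with an estimated correlation). H2-Eb1, H2-Ab1 and H2-Aa, the chains of the peptide-presenting molecules, had log2 fold changes of -2.36 ± 0.09, -2.19 ± 0.11 and -1.96 ± 0.10 (SE; edgeR adjusted p = 1.11e-07 for both H2-Ab1 and H2-Aa). MHC class I presentation fell in 8 of 16 genes and rose in 1, the same adjusted over the list alone (camera adjusted p = 0.00265; adjusted p = 0.385 with an estimated correlation). Its named members were H2-Q7 at -1.02 ± 0.10, a class I gene whose reads can be shared with its H2-Q relatives, Psme2, a proteasome activator, at -0.64 ± 0.07 and Tap1, a peptide transporter, at -0.58 ± 0.08. In the same libraries the summed endothelial markers fell from 5526 ± 527 to 2259 ± 543 CPM (SD, n = 3), and dendritic cell markers did not pass as a list by camera but passed as lower by fry (adjusted p = 0.00304). The summed dendritic cell markers stood at 886 ± 55.8 CPM in KC_EV and 951 ± 16.1 CPM in KC_Epo. Bst2, outside the naming rule and also on the type I interferon list, supplied 307 ± 20.5 and 401 ± 17.8 CPM of these sums. Low-count members can fall within such a sum unseen: Xcr1 went from 10.5 to 1.30 CPM and Flt3 from 8.17 to 2.89 CPM.

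The interferon lists went in opposite directions. Interferon-gamma response genes fell in 14 of 19 cases and rose in 2, the same adjusted over the list alone (camera adjusted p = 0.000234; adjusted p = 0.329 with an estimated correlation). Cxcl9, a T cell attractant, fell by 0.93 on the log2 scale, Nos2, the inducible nitric oxide synthase, had a value of -2.62 ± 0.32 and Tgtp2 one of -1.14 ± 0.12, while Gbp7 rose by 0.69 ± 0.08. Type I interferon response genes rose in 16 of 23 cases and fell in 0, the same adjusted over the list alone (camera adjusted p = 6.06e-06; adjusted p = 0.331 with an estimated correlation), with Irf7 at 0.68 ± 0.09, Mx1 at 0.65 ± 0.07 and Oasl2 at 0.52 ± 0.08. Inflammatory cytokine and NF-kB genes fell in 13 of 22 cases and rose in 4, or 14 and 4 adjusted over the list alone (camera adjusted p = 0.000333; adjusted p = 0.329 with an estimated correlation). Tnf, Il1b and the chemokine Ccl4 had log2 fold changes of -1.61 ± 0.07, -1.29 ± 0.07 and -1.26 ± 0.08. The 4 that rose, outside the naming rule, were Ccl2 at 0.86 ± 0.12, Il18 at 0.78 ± 0.07, Il6 at 0.40 ± 0.10 and Nlrp3 at 0.29 ± 0.08. Proliferation genes fell in 23 of 28 cases and rose in 0, or 25 and 0 adjusted over the list alone (camera adjusted p = 1.57e-08; adjusted p = 0.329 with an estimated correlation), with Top2a at -1.15 ± 0.12, Rrm2 at -1.04 ± 0.11 and Mcm6 at -0.76 ± 0.09.

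Several macrophage and metabolic lists did not pass as a whole, and the genes named here are members that did. The immunoregulatory list had 11 of 22 members higher and 7 lower, or 12 and 8 adjusted over the list alone (camera adjusted p = 0.125; adjusted p = 0.329 with an estimated correlation). Ccl24 rose by 1.03 ± 0.10 and Ccl22 had a value of -2.45 ± 0.18; the list passed with library sizes only (adjusted p = 0.0101). Lipid-associated macrophage genes rose in 4 of 14 cases and fell in 5, or 4 and 6 adjusted over the list alone (camera adjusted p = 0.972), with Trem2 at 1.34 ± 0.11, the lipase Lpl at 1.09 ± 0.09 and Capg at -0.90 ± 0.10. Of 17 monocyte genes 3 rose and 3 fell, or 4 and 5 adjusted over the list alone (camera adjusted p = 0.735), with Plac8 at 0.85 ± 0.10 and F13a1 at -0.89 ± 0.12. Cholesterol biosynthesis had 4 of 21 members higher and 2 lower (camera adjusted p = 0.238), with Insig1 at 0.69 ± 0.10. Hypoxia and glycolysis had 4 of 21 higher and 4 lower, with Hk2 at 0.50 ± 0.07, and oxidative phosphorylation 1 of 22 higher and 1 lower (camera adjusted p = 0.972 for each). The unfolded protein and stress list had 8 of 18 higher and 3 lower, or 8 and 5 adjusted over the list alone (camera adjusted p = 0.238), with Xbp1 at 0.62 ± 0.07 and Herpud1 at -0.64 ± 0.07. Counts adjusted over the list alone equalled these for the cholesterol, hypoxia and oxidative phosphorylation lists. Dissociation and immediate early genes rose in 11 of 17 cases and fell in 3, the same adjusted over the list alone (camera adjusted p = 0.0377; adjusted p = 0.586 with an estimated correlation), and lost the call without KC_EV 1 (adjusted p = 0.0848). Their named members were Zfp36 at 0.97 ± 0.09 and the heat shock genes Hspa1b and Hspa1a, near-identical copies, at -1.63 ± 0.10 and -1.35 ± 0.08. The monocyte and lipid-associated lists had a median above 0 and a mean below 0, as did the immunoregulatory, stress and oxidative phosphorylation lists. The test direction was down for the monocyte and oxidative phosphorylation lists and up for the other 3.

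**Figure D2:**
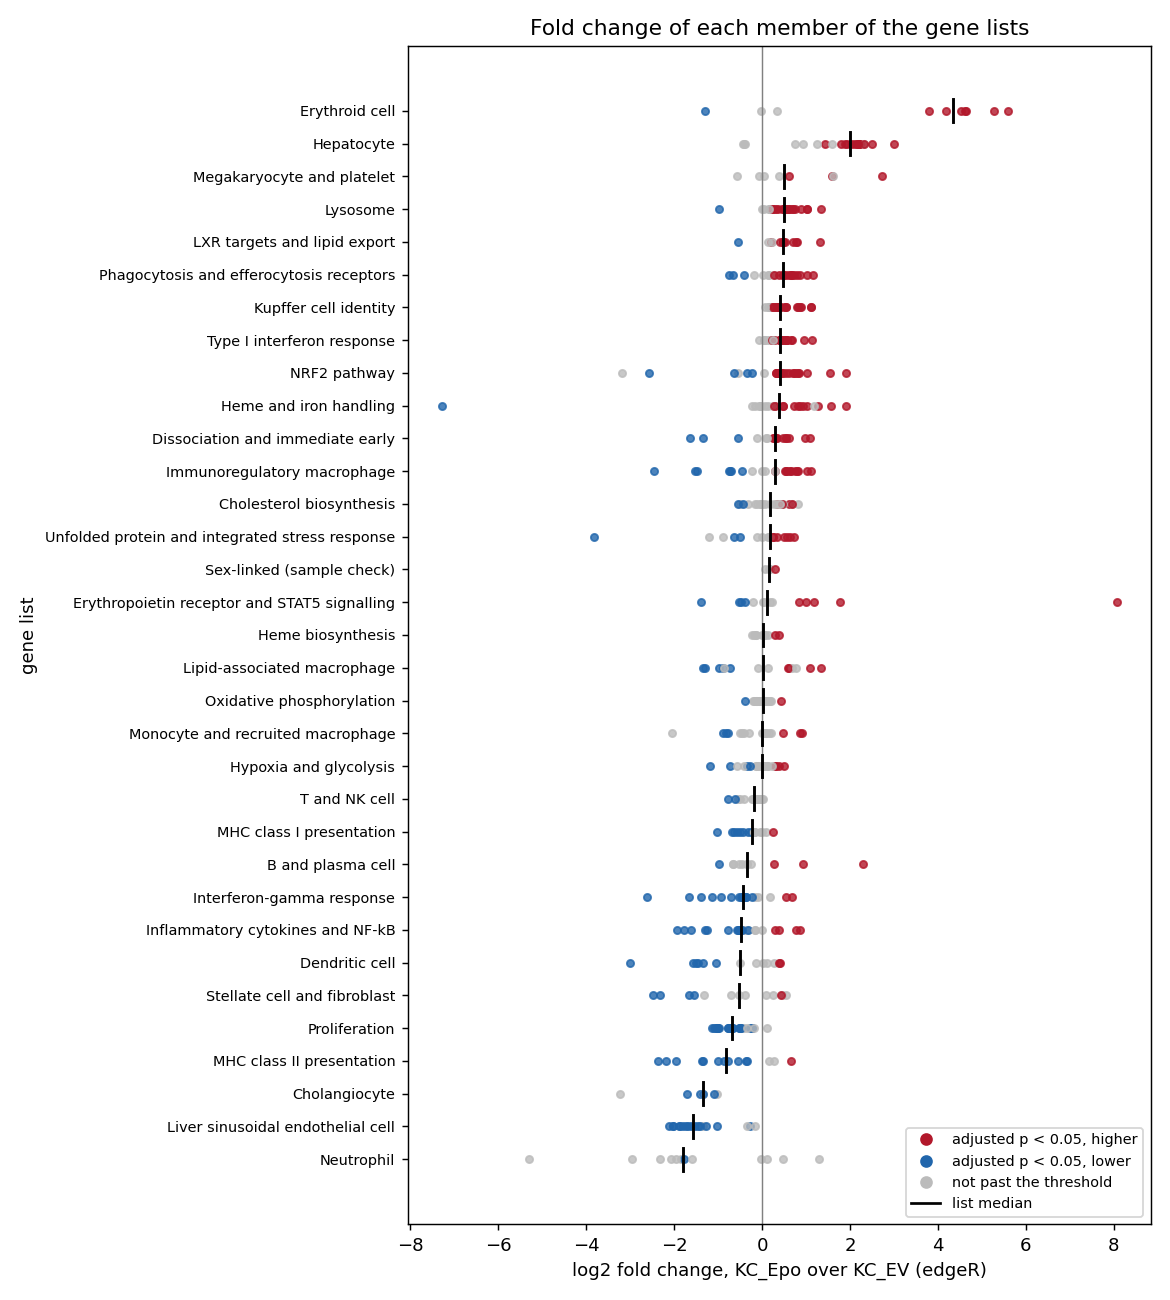
Log2 fold change of KC_Epo over KC_EV for each tested member of the 33 gene lists, with red for members past the threshold and higher, blue for those past it and lower, grey for the rest, and a black bar at the list median. The erythroid list has a median of 4.35 and the endothelial list one of -1.57.

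Markers of other liver and blood cells also moved. Erythroid genes rose in 7 of 10 cases and fell in 1, the same adjusted over the list alone (camera adjusted p = 2.78e-05; adjusted p = 0.329 with an estimated correlation), with a median log2 fold change of 4.35. The hemoglobin chain Hba-a1 rose from 9.84 ± 0.84 to 227 ± 71.4 CPM (SD, n = 3), and Slc4a1, the red cell anion exchanger, had a log2 fold change of 5.27 ± 0.59. Hepatocyte genes rose in 14 of 22 cases and fell in 0, or 17 and 0 adjusted over the list alone (camera adjusted p = 1.45e-05; adjusted p = 0.492 with an estimated correlation). Their summed level was 4239 ± 460 CPM in KC_EV and 27640, 8193 and 16630 CPM in KC_Epo 1 to 3. Cyp2e1, a cytochrome P450, had a log2 fold change of 3.01 ± 0.51 and Hp, haptoglobin, 2.499 ± 0.45. Both lost the call without KC_EV 1, KC_EV 2, KC_EV 3 or KC_Epo 3, with values of 2.94 to 3.06 for Cyp2e1 and 2.35 to 2.61 for Hp. Apoc3 was at 1.43 ± 0.30, and at 1.47, 1.55 and 1.43 without KC_EV 2, KC_EV 3 or KC_Epo 3, none of which passed. Sinusoidal endothelial genes fell in 15 of 18 cases and rose in 0, or 17 and 0 adjusted over the list alone (camera adjusted p = 1e-07; adjusted p = 0.385 with an estimated correlation), with Ehd3 at -2.12 ± 0.27, Aqp1 at -2.03 ± 0.25 and Dnase1l3 at -1.62 ± 0.19. Cholangiocyte genes fell in 4 of 7 cases and rose in 0, the same adjusted over the list alone (camera adjusted p = 0.00645; adjusted p = 0.329 with an estimated correlation), with Epcam at -1.70 ± 0.43. Their summed level was 74.2 CPM in KC_EV 1 against 35.7 and 34.8 CPM in KC_EV 2 and 3, and 15.3 ± 3.28 CPM in KC_Epo.

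**Figure D3:**
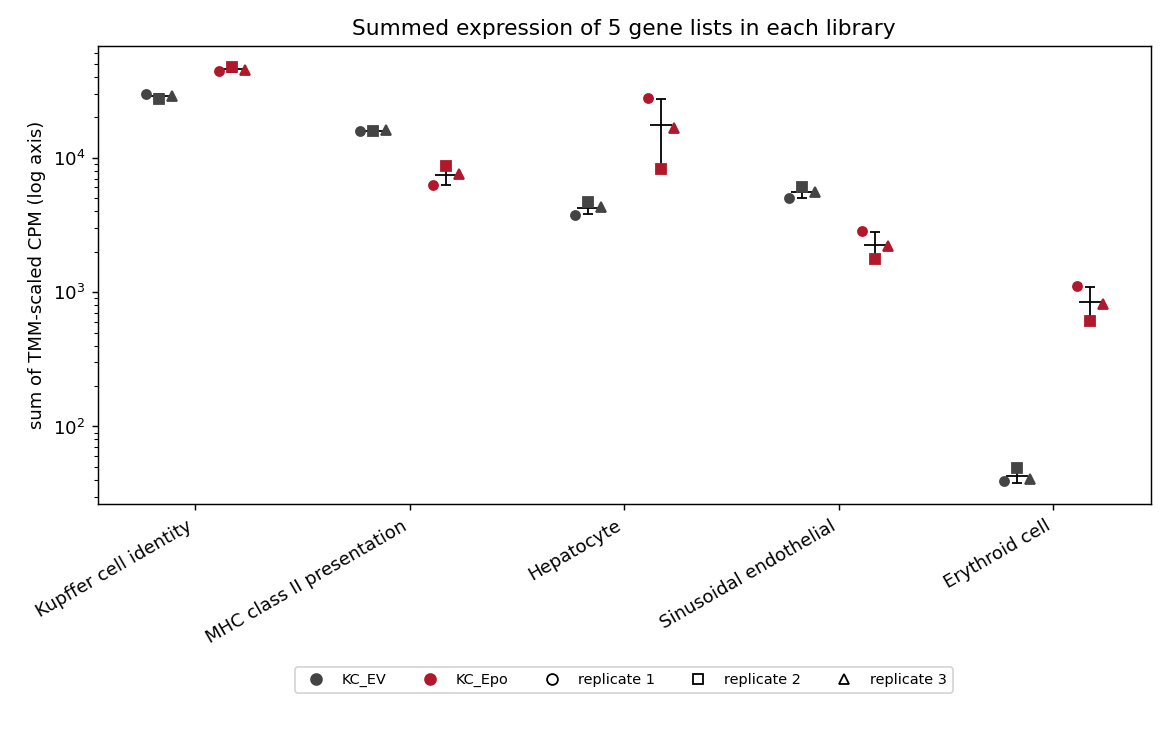
Sum of TMM-scaled CPM over 5 gene lists in each library, on a log axis, with KC_EV in grey and KC_Epo in red; marker shape gives the replicate number and black bars the mean ± SD of 3 libraries. The hepatocyte sum is 27640 CPM in KC_Epo 1 and 8193 CPM in KC_Epo 2, and the endothelial sum 2834 and 1756 CPM.

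The remaining cell type lists did not pass. Dendritic cell genes fell in 6 of 13 cases and rose in 2, or 6 and 3 adjusted over the list alone (camera adjusted p = 0.125), with Xcr1, a chemokine receptor of cross-presenting dendritic cells, at -3.01 ± 0.22, Flt3 at -1.49 ± 0.27 and Cd209a at -1.05 ± 0.18. B and plasma cell genes rose in 3 of 11 cases and fell in 1 (camera adjusted p = 0.667), with Jchain, the joining chain of secreted antibody, at 2.29 ± 0.33 and Mzb1 at 0.94 ± 0.19. T and NK cell genes fell in 2 of 15 cases (camera adjusted p = 0.125), with Lck at -0.77 ± 0.16, and the list passed without KC_Epo 2 (adjusted p = 0.00529). Of 12 neutrophil genes 1 fell, Mmp9 at -1.77 ± 0.20 (camera adjusted p = 0.677), and the list passed as lower without KC_EV 1 (adjusted p = 0.000663). Stellate cell and fibroblast genes fell in 4 of 13 cases and rose in 1 (camera adjusted p = 0.15), with the collagen genes Col1a1 at -2.47 ± 0.15 and Col1a2 at -2.32 ± 0.16, and the list passed without KC_Epo 1 (adjusted p = 0.0452). Megakaryocyte and platelet genes rose in 3 of 8 cases (camera adjusted p = 0.125), with Pf4 at 0.61 ± 0.10, and passed without KC_Epo 2 (adjusted p = 0.0302). The sex-linked list had 1 of 4 members higher (camera adjusted p = 0.226). Counts adjusted over the list alone were the same for these 6 lists. Fewer than 4 members could be tested for mast cells, where Gata2 was at -1.34 ± 0.24, and for Hepa1-6 tumour cells, where Igf2bp3 was at -2.11 ± 0.45 and Epo was the member that rose.

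The largest rises were led by Fgf23, a hormone of phosphate balance, with 1 count in KC_EV and 1388 in KC_Epo. That is a ratio of 1598 with a counting interval of 286 to 63180; its fitted log2 fold change was 10.12, and 9.42 without KC_Epo 1. Without KC_EV 2, the library with that count, the fitted value was 11.91 and the call was lost (adjusted p = 0.0703). Cyp2c69 followed, with 1 and 446 counts, a ratio of 514 and an interval of 91.7 to 20330; its fitted value was 8.51, and 10.30 without KC_EV 1, the library with that count. Fitted values against 0 or 1 count depend on the prior count and are no bounds. Cyp4a14 was at 6.93 ± 1.01, and lost its call without KC_EV 2 (7.05, adjusted p = 0.0517) and with limma-voom (6.88, adjusted p = 0.0627). Orm2, an acute-phase protein, was at 5.46 ± 0.49, Cyp4a10 at 5.10 ± 0.78, Saa2 at 4.70 ± 0.39, Hsd17b6 at 4.56 ± 0.67 and Cyp2c37 at 4.39 ± 0.74. Hbb-bt and Hbb-bs, hemoglobin chains, were at 4.63 ± 0.42 and 4.61 ± 0.30. The Cyp, Orm, Saa and globin genes have close relatives that can share reads. In KC_Epo 1 to 3, Cyp4a14 was at 53.7, 11.1 and 27.0 CPM and Cyp2c37 at 19.1, 5.85 and 13.2 CPM. Saa2 differed less, at 13.8, 8.52 and 11.0 CPM. The hepatocyte sum had the same order, at 27640, 8193 and 16630 CPM. Which cells supplied the transcripts with the largest rises was not tested. Many large changes also differed between KC_Epo libraries. Among genes at 1 CPM or more in KC_Epo, the ratio of KC_Epo 1 to KC_Epo 2 was above 1.5 for 10.6%. It was above 1.5 for 55.9% of 342 such genes up over 2-fold and 61.9% of 583 down over 2-fold. The largest falls were Hs3st2 at -5.26 ± 0.62, Pla2r1 at -3.69 ± 0.22, Tnip3 at -3.58 ± 0.27, Pgm5 at -3.39 ± 0.38 and Dsp, a desmosome gene, at -3.30 ± 0.72. Bmp6, a signal that raises hepcidin, fell from 24.4 ± 2.47 to 2.47 ± 0.72 CPM (SD, n = 3), with Hspb1 at -3.27 ± 0.13, Cav1 at -3.26 ± 0.66 and Acod1, which makes itaconate in activated macrophages, at -3.23 ± 0.16. Adgrg6 and P2ry1 were at -3.17 ± 0.19 and -3.04 ± 0.24. Dsp lost its call without KC_Epo 3 (-3.13) and Cav1 without KC_Epo 2 (-2.91) or KC_Epo 3 (-3.13). Without KC_Epo 1 the values were -4.28 for Dsp, -3.92 for Cav1, 6.25 for Cyp4a14, 4.51 for Cyp4a10 and 3.83 for Hsd17b6. Hs3st2 was at -6.31 without KC_Epo 2, Saa2 at 5.39 without KC_EV 1 and Cyp2c37 at 4.98 without KC_EV 2. Cyp2c37 lost its call with the replicate block (4.33, edgeR adjusted p = 0.0534).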

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

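Of the tests in this part, only the fit without KC_EV 1 and KC_Epo 1 together was chosen after the data were seen; it called 4867 genes. Across the other fits the total ran from 2137 against a 1.2-fold change (961 higher, 1176 lower) to 4805 with library sizes only (1194 higher, 3611 lower), and 0 of the 4234 calls changed sign in any fit. The 1.2-fold test asks for a larger change by construction; the cause of the other shift was not tested beyond the moved median of all genes. Leaving out 1 library gave 2728 to 4557 genes, 1477 to 2410 higher and 1251 to 2147 lower, with fewer samples in each fit. DESeq2 called 4458 and limma-voom 4180. With an estimated correlation camera called 0 lists higher and 0 lower, against 10 and 7; 17 lists had passed. At fixed correlation the called lists kept their direction in each fit in which lists were tested, which leaves out the non-robust fit, the 1.2-fold test, DESeq2 and limma-voom. By fry the hepatocyte (adjusted p = 0.0604) and dissociation (0.15) lists did not pass, and the latter also failed without both libraries (0.0551). Fry called 12 lists higher and 9 lower. It gained the receptor and STAT5 (0.0011), immunoregulatory (0.0026), cholesterol (0.0401) and sex-linked (0.047) lists as higher, and the dendritic (0.00304) and stellate (0.047) lists as lower. Fry does not compare a list with other genes. The receptor and STAT5 list holds Epo, which the tumour cells overexpressed, and 4 of its 14 tested members fell. That list was not tested without Epo.

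Correlations of same-numbered deviations from the group means were -0.11, -0.15 and -0.041, which gave no sign of pairing. They cannot exclude it, as the deviations of 3 libraries sum to 0 within a group. With the replicate block 3358 genes passed, 3311 of them among the 4234, and T and NK cell genes passed as lower.

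Over 123 named genes, 101 kept direction and side in every fit. Spic alone turned, at -0.029 with library sizes only. In 19 cases a list not called in the comparison turned its tested direction; causes were not tested, and values are list medians. With library sizes only the monocyte (-0.15), B cell (-0.51) and neutrophil lists (-1.97) turned from down to up, although these medians lay below 0. Hypoxia genes turned from down to up under fry, with the median unchanged at -0.0012. They also turned without a filter (0.0070) and without KC_EV 1 and KC_Epo 1 together (0.0059). Their median ran from -0.013 to 0.021 with 1 library left out. Oxidative phosphorylation gave 0.021 without a filter, 0.037 without both libraries and -0.039 to 0.050 with 1 left out. Lipid-associated genes gave 0.011 without both and -0.021 to 0.090 with 1 left out. Heme biosynthesis ran from -0.019 to 0.082 and neutrophil genes from -2.39 to -0.92. Depth limits Epo, Fgf23 and Cyp2c69, each with at most 1 count in KC_EV.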

Other observations

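Of the tests in this part, the count of splits was planned before its result was seen, and the other tests were chosen after. Hamp and the genes named without a list here, and the contrast of the interferon lists, were also chosen after their values were seen. Hamp, the iron hormone hepcidin made by hepatocytes, had 242 counts in KC_EV and 1 in KC_Epo, a ratio of 210 with a counting interval of 37.4 to 8334, while Alb, albumin, rose from 1752, 2128 and 1950 CPM to 14660, 3995 and 8586 CPM. Fgf23 stood at 28.4, 7.72 and 12.03 CPM in KC_Epo 1 to 3, in the same order as Alb. The erythroid sum (1113, 608 and 813 CPM) and the endothelial sum (2834, 1756 and 2185 CPM) had that order too, so it points to no particular cell type. Ciita, the master regulator of MHC class II genes, had a log2 fold change of -1.36 ± 0.08 (edgeR adjusted p = 3.55e-07), and Cd74, the invariant chain, -1.35 ± 0.14.

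The mean log2 CPM of 23 type I interferon genes minus that of 19 interferon-gamma genes was 0.40 ± 0.03 in KC_EV and 1.35 ± 0.10 in KC_Epo (SD, n = 3 each). The difference was 0.95, with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries can give. KC_EV 1 stood apart in a few genes: Nqo1 was at 23.8 CPM there and 0.99 and 0.50 CPM in KC_EV 2 and 3, and Krt7 at 35.6 against 3.68 and 4.28 CPM. Elane, a neutrophil gene, was at 0.32 CPM there and at 18.95 and 37.3 CPM in KC_EV 2 and 3.

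Of the 10 splits of the 6 libraries into 3 against 3, 1 gave as many genes as the real groups, the real one itself, with 4234. The highest of the other splits by edgeR gave 0, with at most 437 genes at an unadjusted p under 0.05. So few splits cannot give a share under 0.05.

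Hepatocyte transcripts were higher in KC_Epo. A hepatocyte profile that was alike in both groups is argued against only if hepatocytes supplied all of this RNA. On that condition 16 of the 22 members changed relative to the list total (edgeR, adjusted over the list), 7 of them upward, and Hamp fell while Alb rose. Kupffer cells or tumour cells may also supply some members, which was not tested. The lowest members relative to the total were Ass1 at -2.48 and Cps1 at -2.47. More hepatocyte RNA in the KC_Epo sorts remains a candidate explanation: the 22 members had a median ratio of 3.19 between KC_Epo 1 and KC_Epo 2, where all genes had a median of 0.99 and genes up over 2-fold one of 2.01. The sort for Kupffer cells would be meant to remove hepatocytes, and 21 of the 22 members stood above 10 CPM in KC_EV as well. A changed hepatocyte expression in these mice, carried with that RNA, may add to it and was not separated from it.

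Sinusoidal endothelial transcripts were lower in KC_Epo. The 18 members shared a library profile, with a median ratio of 1.94 between KC_Epo 1 and KC_Epo 2, as less endothelial RNA in the KC_Epo sorts would give, but not one particular to them: all genes had a median of 0.99, genes down over 2-fold 1.69 and erythroid members, which rose, 1.84. An endothelial profile alike in both groups is argued against only if endothelial cells supplied all of this RNA. On that condition 9 of the 16 members with a ratio above 1.5 changed relative to their total, 5 of them upward. Kupffer cells may express some members, which was not tested. Stab2, which was not among the 16, was at -0.27 ± 0.09. All 18 members stood above 10 CPM in KC_EV. A lower share of Kupffer cells in the sort would raise every other cell type alike, and a higher share would lower them alike. Hepatocyte and endothelial sums moved apart, 4.13-fold and 0.409-fold, so neither alone gives both. The Kupffer identity sum rose 1.59-fold, as a higher share would give. A higher share beside more hepatocyte RNA was not tested and stays open. Changed expression within endothelial cells may also take part and stays open.

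MHC class II genes were lower in KC_Epo. Fewer endothelial cells as the whole source are not decided here. The highest ratio between KC_Epo 1 and KC_Epo 2 among H2-Aa, H2-Ab1 and H2-Eb1 was 0.815, where all 18 endothelial members had a lower quartile of 1.81. That ratio describes only the RNA left in KC_Epo, which macrophages may supply, and not the part that was lost. By size, H2-Eb1 at -2.36 and H2-Ab1 at -2.19 fell past the endothelial median of -1.57. The lowest endothelial member, Ehd3, was at -2.12 ± 0.27, past H2-Aa at -1.96. Fewer B cells as the whole source are argued against by the size of the fall, since the lowest member, Ebf1, was at -0.98 ± 0.28 and H2-Aa at -1.96. The median ratio of that list, 0.544, lay below 1 as the MHC class II ratios did, but these too describe only what was left. Fewer dendritic cells cannot be told apart from a fall within macrophages. The 13 members had a mean of -0.72, with a 95% interval of -1.34 to -0.097 over genes and not over libraries. That mean cannot weigh against it, as macrophages may express some members, such as Bst2 at 0.39, also on the type I interferon list. Xcr1, 1 of the 13, fell by 3.01, further than H2-Aa, with a ratio of 1.53 at few counts. The 13 shared no library profile, with a lower quartile of 0.915 where all genes had an upper quartile of 1.14. A lower interferon-gamma response in the sorted macrophages is a hypothesis that no test here decides, with a list median of -0.44 but an adjusted p of 0.329 with an estimated correlation, and Ciita is itself on the MHC class II list.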
